A study of Mus musculus with 46 samples.

How the data were processed

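RNA was measured in kidney and liver of wild-type C57BL/6 mice that were castrated or sham operated at 8 weeks of age and sampled at 12 weeks or 18 months. Per the labels' protocols, RNA was isolated with Trizol, polyadenylated RNA was enriched, and paired-end libraries with reads of 150 bp were sequenced on a DNBSEQ instrument. The 46 libraries form 12 groups by age, tissue and arm. Each sham male and sham female group holds 3 libraries, and the castrated male groups hold 6 libraries at 12 weeks and 5 at 18 months. Metabolites of kidney, liver and serum were measured by untargeted metabolomics in the same 3 arms at both ages.

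Per the submitters' processing notes, HISAT2, SAMtools and Cufflinks were used with the mouse genome build mm10. Their versions, roles and settings are not given in the sources used here. For the 12-week RNA, the authors deposited FPKM (fragments scaled by transcript length and library total) as 1 mean per group for 17242 genes, and the labels name this unit. From the values, 0.01 had been added to every mean, so a gene at 0.01 was listed at 0. Per the file headers, the 12-week comparison tables hold a test statistic (score), a p-value and an adjusted p-value, in the column layout of Cuffdiff. Each gene has a single entry in these deposited tables, for 1 of the 3 comparisons, by a rule that is not stated. Of the 17242 genes, 5598 are listed for castration, 3200 for sex and 8444 for castrated males against females in kidney, and 8479, 628 and 8135 in liver. Genes and list members listed for another comparison were counted as not called, so counts at 12 weeks are lower bounds, and the listing itself may select genes. For the 18-month RNA, the authors deposited a normalized expression signal as 1 mean per group for 18531 genes, and its unit is not named. Per the file headers, the 18-month comparison table holds log2 fold changes, p-values and adjusted p-values from the authors' DESeq2 tests of every comparison. The metabolite tables hold 1 mean relative abundance per group for each compound named by its fragment spectrum, per the file headers. Their scale, normalization and numbers of animals are not given in the sources used here.

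The depth per library is unknown, since the values used here are group means. For the same reason no test across libraries was computed here, no library was left out in turn, no outlier was sought, and no other split of the libraries was tried. The planned tests per library were replaced by the authors' own tests, as the design made before the data were examined provides for this case. A gene was called when the authors' adjusted p was under 0.05, with its direction from the group means at 12 weeks and from the authors' log2 fold at 18 months. Benjamini-Hochberg adjustment within a gene list was computed from the authors' p-values. At 12 weeks only members listed for that comparison could enter it. A 12-week count equal to that over all genes is thus largely fixed by the listing and adds no support. The 2 ages were processed separately, so nothing was tested between them.

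Within each age and tissue, 3 comparisons were made, each as a difference of log2(mean + 1). They were castrated males minus sham males (castration), sham females minus sham males (sex), and castrated males minus sham females (residual difference). The added 1 understates the fold of genes with low means. Abundant genes listed at 0 in a group while another group of the tissue had a mean of at least 1000 were taken as failed estimates and given no difference against that group. This rule, chosen after the data were seen, applied to Gpx3 and Kap in 12-week kidney and to Apoe, Serpina1b and Serpina1d in 12-week liver. It cannot detect a gene listed at 0 in every group, such as Alb in 12-week liver, or a failed estimate below that mean, so other means listed at 0 may also be failed estimates. At 18 months an error was implied from the authors' table as the absolute log2 fold divided by the normal quantile of its p-value. This step was also chosen after the data were seen. The median implied standard error over genes with a mean of at least 5 was 0.109 for castration, 0.129 for sex and 0.113 for the residual difference in kidney. In liver it was 0.237, 0.189 and 0.236.

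Genes named in the text follow a rule set before the data were examined. For castration, it takes the 10 largest rises and 10 largest falls among called genes with a larger mean of at least 5. For the other comparisons it takes 5 in each direction, and members of fixed lists may be named as examples. The 44 gene lists were fixed before the data were examined, from textbook knowledge of kidney, liver, sex-biased expression and possible neighbouring tissues. Each list's median difference was placed among 10000 random lists matched on mean expression in 20 bins. Random lists draw genes singly and do not carry variation that list members share, so a percentile is not a p-value. Gene positions come from the GENCODE vM21 annotation of mm10, in which all 109 named genes matched a single gene.

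For genes called for sex, the share whose castrated male mean lay on the female side of the sham male mean was counted. The fraction of the sex difference reached after castration was computed as well. Both contrasts use the same sham male libraries, so the share in a castrated group equal to sham males was simulated in 100 draws. The simulation at 12 weeks used the authors' scores with a minimum chosen after the data were seen. Overlaps between tissues or ages were compared with the number of shared genes that independence gives. Their Spearman correlations were taken over all genes with a mean of at least 5, after a version over tested genes was seen. All entries of the metabolite tables were compared as log2 ratios of group means, and each carried a name except in 12-week serum, where 1493 of 1495 did. Differences of at least 2-fold were counted without a test.

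The calling and list steps were tested on simulated data for the 18-month kidney castration comparison. With 200 of 12803 genes changed, 72.0% were recovered at 1.5-fold, 91.5% at 2-fold and 98.5% at 4-fold. False calls made up 3.4%, 4.2% and 3.0% of those called. Errors were normal and independent with the implied standard errors, which the calling step took as known. The false share thus follows from the Benjamini-Hochberg adjustment, and the authors' own tests were not examined by it. Of 200 random lists of 20 genes, 9.5% had a percentile under 5 or over 95. Alternatives were a stricter threshold of 0.01, an added condition on the log2 fold, another pseudocount of 0.1, filters on the mean, centring on the median gene, another metabolite fold of 1.5 and, chosen after the data were seen, a subtraction of genes of like GC content from the list medians of castration. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with random seed 20240.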

Results

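RNA of kidney and liver was compared among castrated males, sham-operated males and sham-operated females of the C57BL/6 strain. Surgery took place at 8 weeks of age and tissues were taken at 12 weeks or 18 months. The stated purpose of the series was to relate castration to sex differences in healthy ageing. The 46 libraries comprised 3 per sham group, 6 per tissue of castrated males at 12 weeks and 5 per tissue at 18 months. Values are the authors' group means without a spread, in FPKM at 12 weeks and in an expression unit that is not named at 18 months. "Rose" and "fell" refer to genes past the authors' adjusted p threshold of 0.05 and differences are of log2(mean + 1). Beside them stand counts by a 2-fold limit on mean + 1 over all genes with a mean of at least 1 in a group, chosen after the data were seen and without a test. How many animals shared a direction is not given in the sources used here, and the depth is unknown.

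Y-linked genes followed the labelled sex in every tissue. Eif2s3y, a translation initiation subunit encoded on the Y chromosome, had 12-week kidney means of 50.4 FPKM in sham males, 74.2 in castrated males and 0.0209 in females. In 18-month liver its means were 37.4, 38.8 and 0.0533.

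In 12-week kidney, Acsm3, a mitochondrial medium-chain acyl-CoA synthetase, fell after castration from a mean of 722 FPKM in sham males to 15.7 in castrated males, with 2.09 in females. Its relative Acsm2 fell from 3800.2 to 372 FPKM. Cyp2e1, a cytochrome P450 that oxidizes ethanol, fell from 1003.5 to 114.5 FPKM, and the female mean was 31.3. Odc1, the rate-limiting enzyme of polyamine synthesis, fell from 177 to 23.5 FPKM. The protease inhibitor gene Pzp fell from 97.8 to 0.819 FPKM, and the glucuronosyltransferase gene Ugt1a9 from 142 to 1.35. Ugt1a genes share exons, so the split of reads among them is uncertain. Slc22a7, an organic anion transporter, fell from 78.9 to 3.45 FPKM although its female mean was 96.0. Solute carriers of the proximal tubule as a list fell in 4 and rose in 2 of 20 members, with a median at percentile 58.1 of random lists of like expression and equal counts adjusted over the list alone. Cndp2, a dipeptidase, fell from 755 to 110.4 FPKM, and Degs2, a sphingolipid desaturase, from 29.8 to 3.10.

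Prlr, the prolactin receptor (mm10 chromosome 15, 10177238 to 10349180), rose in the same kidneys from 3.03 to 39.3 FPKM, with 42.5 in females. Hpd, a dioxygenase of tyrosine breakdown, rose from 46.4 to 336 FPKM, with 409 in females. The lipoprotein component Apoe rose from 164 to 942 FPKM and the acyl-CoA thioesterase Acot3 from 6.17 to 32.6. Ceruloplasmin, encoded by Cp, rose from 21.2 to 73.1 FPKM. Ugt1a10 rose from 16.1 to 235 FPKM with a female mean of 15.8. In total 1264 genes rose and 1458 fell among the 5598 genes listed for castration, and by the 2-fold limit 310 were higher and 449 lower. The median gene with a mean of at least 1 differed by 0.022.

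Of 18 measured male-biased kidney genes, 7 were listed for castration and all 7 fell, and the list median was -2.92. Of 11 female-biased kidney genes, 4 were listed for castration and all 4 rose, with a list median of 1.71. In every 12-week list count, members listed for another comparison count as not called. These counts are therefore not comparable with those at 18 months. Heat shock and chaperone genes were lower in castrated males, with 12 of 16 down, 1 up and a median of -0.89. Hsp90aa1, an inducible cytosolic chaperone, fell from 149 to 31.3 FPKM, and the mitochondrial chaperone Hspd1 fell from 160.2 to 67.0. Of 18 clock genes, 6 rose and 3 fell, among them Per1, which rose from 13.1 to 29.2 FPKM, and Clock, which fell from 3.96 to 2.97. Of 18 collagen and matrix genes, 7 were listed for castration and all 7 rose, with a list median of 0.69. Col1a2 rose from 11.04 to 28.1 FPKM and the pericyte receptor Pdgfrb from 7.43 to 20.2. Cholangiocyte and stellate cell genes rose in 6 of 13 members, with a median of 0.65, and endothelial genes in 3 of 13, with a median of 0.20 at percentile 95.96, and 0 of either fell. Oxidative phosphorylation genes fell in 8 of 22 members and rose in 1, with a median of -0.48 at percentile 2.84 of random lists, and Atp5b, a catalytic subunit of ATP synthase, fell from 2708 to 1566 FPKM. Glutathione and NRF2 target genes fell in 9 of 27 members and rose in 1. Prdx1, a peroxide reductase, fell from 812 to 221 FPKM, and heme oxygenase, encoded by Hmox1, from 20.4 to 5.15. Cholesterol synthesis genes fell in 5 of 24 members. Adjusted over the list alone, 7 cholesterol synthesis genes fell, 2 glutathione genes rose, and the other list counts in this paragraph were equal to those over all genes. Only members listed for castration entered this adjustment.

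Between females and sham males in 12-week kidney, Slc7a13, an amino acid transporter of the proximal tubule, had the largest difference among genes named by the rule. Its mean was 347 FPKM in sham males, 0.242 in females and 21.6 in castrated males. The glucuronosyltransferase Ugt2b38 was lower in females, at 9.81 against 634 FPKM, and Cyp7b1, a hydroxylase of oxysterols, at 1.32 against 66.8. Igf2, a fetal growth factor, was higher in females at 71.3 against 0.853 FPKM, and its castrated male mean was 1.23. Slc7a12, a female-biased amino acid transporter, was higher at 89.5 against 2.51 FPKM, and Slc22a29, an organic anion transporter family member, at 133 against 4.41. Among the 3200 genes listed for sex, 1336 were higher and 1269 lower in females, while the 2-fold limit gave 583 and 624. Of 17 interferon response genes, 9 were listed for sex and all 9 were higher in females, with a list median of 0.58. Adjusted over the list alone, the count could only be equal. Castrated males and females differed directly at 434 genes, 269 higher and 165 lower in castrated males, against 53 and 66 by that limit. The androgen-regulated kidney protein Kap was lower, at 689 FPKM against 27835 in females. Its sham male mean is listed at 0 and was set aside as a failed estimate. Cyp4b1, a fatty acid hydroxylase, was higher in castrated males at 217 against 70.1 FPKM, and the acetyltransferase gene Nat8 at 133 against 44.8.

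In 18-month kidney, Kap (mm10 chromosome 6, 133849851 to 133853762) fell from a mean of 74818 expression units in sham males to 816 in castrated males, with 25377.5 in females. The authors' deposited table gives Kap a log2 fold of -6.65 with an implied standard error of 0.427 and an adjusted p = 5.66e-52 by their DESeq2 test. Slc7a13 fell from 612 to 9.32, and Cyp2j13, an arachidonic acid epoxygenase, fell from 150 to 1.08. Slco1a1, an organic anion uptake carrier, fell from 64.8 to 0.044, and its female mean was 0.02. Ugt2b37 fell from 92.8 to 1.40, and Ugt8a, the galactosyltransferase that makes galactosylceramide, fell from 43.9 to 1.47. Akr1c14, a hydroxysteroid dehydrogenase, fell from 100.4 to 5.36 with a female mean of 34.7. Slc22a30 fell from 157 to 10.5, Acsm3 from 183 to 13.6 and Pzp from 36.9 to 1.13.

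Ugt1a2 rose from 0.807 to 682 in 18-month kidney, against 684 in females, and the authors' deposited table gives it a log2 fold of 9.62 with an implied standard error of 0.607. Ugt1a8 stood at 0.01 in sham males and females and at 132 in castrated males. Their shared exons leave the split of reads within the Ugt1a family uncertain. Gsta4, a glutathione transferase for lipid aldehydes, rose from 38.8 to 381, with 373 in females. Bhmt, which methylates homocysteine from betaine, rose from 7.56 to 92.6, above the female mean of 25.7. The vitamin D binding protein gene Gc rose from 28.2 to 255 with a female mean of 68.3. Slc22a29 rose from 2.77 to 36.6, and Gsta1 from 0.817 to 14.1. Castration raised 1708 genes and lowered 2343 of 17872 tested, whereas the 2-fold limit gave 177 higher and 147 lower. At this age the median gene with a mean of at least 1 stood 0.127 higher in castrated males and 0.107 higher in females than in sham males. List medians are therefore placed among random lists of like expression, which carry that shift. The 2-fold counts rest on the means and carry it too, while the authors' folds behind the calls need not. For the 6 genes flagged below, the authors' log2 folds for castration were lower than the log2 ratios of the means in both tissues.

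Male-biased kidney genes fell in 18 of 19 members, with 0 rising and a median of -2.32. Female-biased kidney genes rose in 9 of 11 members, and the member that fell was Cyp2a4, from 687 to 142. Cytosolic ribosomal protein genes rose in 23 of 27 members, with a median of 0.42 at percentile 99.99 of random lists. Rps18 rose from 947.5 to 1327 and Rpl23 from 333 to 482. Genes of nephron segments other than the proximal tubule rose in 11 of 17 members, with a median of 0.61. Umod, made by the thick ascending limb, rose from 1091 to 1585, the distal tubule calcium buffer Pvalb from 17.8 to 47.2, and the salt cotransporter Slc12a3 from 293 to 487. Antigen presentation genes rose in 9 of 13 members, with a median of 0.73. Cd74, the invariant chain of class II molecules, rose from 357 to 594, and B2m, the light chain of class I, from 500.5 to 934. Endothelial genes rose in 5 of 13 members, with a median of 0.49, cholangiocyte and stellate cell genes in 4 of 13, with a median of 0.42, and blood markers in 3 of 11, with a median of 0.47, and 0 of these fell. T cell, B and plasma cell, and macrophage markers had medians of 0.46, 0.67 and 0.27, all at percentile 99.48 of random lists or higher, with 1 of 12, 1 of 8 and 1 of 18 members rising and 1 macrophage marker falling. Fatty acid oxidation and PPAR alpha target genes rose in 12 and fell in 4 of 27 members. Cyp4a14 rose from 104 to 648, and the fatty acid binding protein Fabp1 from 6.03 to 45.5. Cholesterol synthesis genes fell in 12 of 24 members, and Idi1 fell from 66.6 to 27.3. Kidney injury genes rose in 9 and fell in 3 of 18 members. Osteopontin, encoded by Spp1, rose from 695 to 1758 and the complement component C3 from 12.7 to 37.0, while Il34 fell from 16.3 to 4.98. Adjusted over the list alone, 25 ribosomal, 12 nephron segment, 11 antigen presentation, 8 endothelial, 4 cholangiocyte and stellate, 3 blood, 1 B and plasma cell, 1 macrophage, 0 T cell, 13 fatty acid oxidation and 10 injury genes rose. By the same adjustment 0 macrophage, 1 nephron segment, 5 fatty acid oxidation and 13 cholesterol genes fell.

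Slc7a13, Cyp2j13, Acsm3 and Slco1a1 were among the genes lower in females than in sham males in 18-month kidney. Akr1c18, a progesterone-reducing enzyme, was higher in females at 85.6 against 0.663 in sham males and 0.338 in castrated males. Hdc, which makes histamine, was higher at 96.2 against 3.42, with 3.11 in castrated males. Igf2 was higher at 71.2 against 0.7, and the conjugate exporter Abcc3 at 40.3 against 0.967. Females had 1395 genes higher and 1569 lower of 17625 tested, against 296 and 204 by the 2-fold limit. Of 17 genes of other nephron segments, 12 were higher in females and 0 lower, also adjusted over the list alone, with a median of 0.80. Of 27 ribosomal protein genes, 0 were called in either direction by the authors' DESeq2 test, over all genes or adjusted over the list alone. Their median was 0.23, at percentile 99.94 of random lists, so the list lay above sham males in females too. Castrated males and females differed directly at 1277 genes, 488 higher and 789 lower in castrated males, and by the 2-fold limit 116 were higher and 116 lower. Akr1c18, Kap, Hdc, Igf2 and the lipid transfer gene Sec14l3 led those lower in castrated males. The last had means of 0.5 in castrated males and 11.8 in females. T cell, B and plasma cell, and antigen presentation genes were higher in castrated male than female kidneys in 2 of 12, 1 of 8 and 2 of 13 members. Adjusted over the list alone these were 8, 2 and 11, with medians of 0.56, 0.66 and 0.57 and 0 lower. Of 18 macrophage markers, 1 was higher and 1 lower. Blood markers were higher in castrated male than female kidneys in 6 of 11 members, also adjusted over the list alone, with a median of 0.82. Hba-a1, an alpha globin, stood at 1059.5 in castrated males, 545 in females and 687 in sham males.

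In 12-week liver, transcripts of several major urinary proteins, which bind pheromones in male urine, fell to low levels after castration. Mup20 fell from 4693 to 79.0 FPKM, with 44.4 in females. Mup14 fell from 2594 to 0.526 and Mup11 from 1005 to 1.995 FPKM. Mup genes are near-identical copies, so the split of reads among them is uncertain. Elovl3, an elongase of very long fatty acids, fell from 251 to 0.513 FPKM, with 0.661 in females. Hsd3b5, a male-biased steroid dehydrogenase, fell from 203 to 4.06 FPKM and the fatty acid hydroxylase Cyp4a12a from 117.5 to 1.26.

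Cyp2b9, a female-biased cytochrome P450, rose in 12-week liver from 0.0486 to 228.5 FPKM, with 155 in females. Cux2 (mm10 chromosome 5, 121856366 to 122050102), a female-biased transcription factor, rose from 0.260 to 41.9 FPKM, with 30.0 in females. The metal-binding metallothioneins Mt1 and Mt2 rose from 21.6 to 699.7 and from 3.95 to 154.5 FPKM. Hamp2, a hepcidin gene, rose from 227 to 4804 FPKM, with 6928 in females. Cyp2a22 rose from 1.27 to 110.5 FPKM, Cyp2c69 from 1.29 to 69.3, and Cyp2c40 from 3.68 to 65.5. The organic anion transporter family member Slc22a26 rose from 0.341 to 86.1 FPKM, and the monooxygenase Fmo2 from 5.45 to 85.6, against 29.4 in females. In total 1023 genes rose and 1086 fell among the 8479 listed for castration, with 240 higher and 283 lower by the 2-fold limit, and the median gene differed by -0.019.

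Of 24 male-biased liver genes, 14 were listed for castration and all 14 fell, with a list median of -3.71. Gstp1, a glutathione transferase, fell from 2467 to 213 FPKM, and Selenbp2, a selenium-binding protein, from 461 to 26.3. Of 30 female-biased liver genes, 12 were listed for castration and all 12 rose, with a list median of 1.80. Heat shock genes fell in 8 of 16 members and rose in 0, with a median of -0.66, and the endoplasmic reticulum chaperone Hspa5 fell from 359 to 194. Clock genes rose in 7 and fell in 3 of 18 members. Per3 rose from 5.14 to 42.0 FPKM and Ciart from 5.85 to 30.6, while Arntl, which encodes the clock activator BMAL, fell from 3.11 to 0.477. Immediate early and stress genes rose in 8 of 17 members and fell in 0, among them Egr1 from 2.52 to 43.4. Interferon response genes rose in 11 of 17 members, with a median of 0.56, and Ifit3 rose from 4.95 to 11.7. Antigen presentation genes rose in 6 of 13 members, with H2-Aa going from 17.4 to 36.5. Macrophage markers rose in 5 of 18 members, with a median of 0.34, B and plasma cell markers in 4 of 8, with a median of 0.835, and T cell markers in 2 of 12, with a median of 0.45, and 0 of these fell. Glutathione and NRF2 target genes fell in 10 of 28 members and rose in 1. Cholesterol synthesis genes fell in 7 of 24 members, including Sqle, squalene epoxidase, from 25.1 to 7.56, and rose in 1. Adjusted over the list alone, 8 clock and 12 interferon genes rose, and the other list counts in this paragraph were equal to those over all genes. Only members listed for castration entered this adjustment.

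Females differed from sham males in 12-week liver at 628 genes, 296 higher and 332 lower, and every gene listed for sex in this table was called. The 2-fold limit over all genes gave 320 higher and 237 lower. Sult2a1, a sulfotransferase of steroids and bile acids, was higher in females at 147 FPKM, with 0.0784 in castrated males, and its sham male mean is listed at 0. Cyp3a41a was higher at 16.7 FPKM, with 0.015 in castrated males and sham males listed at 0. A mean listed at 0 in these tables can be a failed estimate, so these zeros need not mean absence. Srebf1, a regulator of lipid synthesis, was higher at 356.5 against 97.4 FPKM. The epidermal growth factor receptor Egfr was lower in females at 18.7 against 122 FPKM, the sterol regulator Insig2 at 18.5 against 98.9, and the steroid reductase Srd5a1 at 7.48 against 40.5. Castrated males and females differed directly at 383 genes, 144 higher and 239 lower in castrated males, and at 41 and 63 by the 2-fold limit. Sult2a2 was lower in castrated males at 0.329 against 305 FPKM in females, A1bg at 1.19 against 34.9, Cyp17a1 at 1.99 against 46.7 and Sult3a1 at 2.98 against 53.0. Of the 30 members of the female-biased list, 13 were listed for this comparison. Of these, 10 were lower and 1 higher in castrated males than in females, with a list median of -0.95. Macrophage markers were lower in castrated males than in females in 6 of 18 members, with a median of -0.52. Both list counts were equal adjusted over the list alone, which only members listed for this comparison entered.

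In 18-month liver, Mup7 (mm10 chromosome 4, 60066469 to 60070475) fell from a mean of 12404 expression units in sham males to 3.63 in castrated males, with 1.003 in females. The authors' deposited table gives Mup7 a log2 fold of -11.83 with an implied standard error of 1.07. Mup20 fell from 14460.3 to 250.1, and Serpina1e, a male-biased protease inhibitor, fell from 5057 to 24.9. Hsd3b5 fell from 87.0 to 0.082 and Slco1a1 from 105 to 0.458. Sult2a2 rose from 0.313 to 1015, with 1499.9 in females. In the authors' deposited table the log2 fold of Sult2a2 was 11.58 with an implied standard error of 0.586 and an adjusted p = 1.16e-82 by their DESeq2 test. Sult2a1 rose from 0.17 to 394, with 1207 in females, and Cyp3a41a from 0.227 to 438, with 1662 in females. A1bg, a secreted immunoglobulin-like protein, rose from 0.123 to 156.5, with 562 in females. Cyp2b13 rose from 0.527 to 290.4, Cyp2a4 from 1.98 to 309.9 and Cyp2c69 from 1.95 to 346. Sult3a1 rose from 0.147 to 70.9, above the female mean of 36.5, and Sult2a5 from 0.0367 to 68.9. Sult2a and Cyp3a41 genes have close copies, so their split of reads is uncertain.

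Castration raised 182 and lowered 171 of 16883 genes tested in 18-month liver, whereas the 2-fold limit gave 255 higher and 98 lower. The median gene stood 0.127 higher in castrated males and 0.139 higher in females than in sham males. The 2-fold counts for castration and sex rest on these means and carry the shift, while the authors' folds behind the calls need not. Called and 2-fold counts are thus not alike in their scaling at this age. The implied standard errors of the castration comparison were a median 1.178 times those of the sex comparison, where the library numbers alone would give 0.894. Male-biased liver genes fell in 23 of 24 members, with 0 rising and a median of -3.61. Female-biased liver genes rose in 26 of 30 members, with 0 falling and a median of 3.34. Fatty acid oxidation and PPAR alpha targets rose in 5 of 27 members and fell in 0. Cyp4a14 rose from 182 to 1048, with 318 in females, and Acot3 from 9.62 to 105.5. Complement genes fell in 6 of 19 members and rose in 1. T cell markers rose in 2 of 12 members and antigen presentation genes in 1 of 13, with medians of 0.56 and 0.53. Macrophage, B and plasma cell, and blood markers had medians of 0.55, 0.965 and 0.81, with 0 members rising and 1 blood marker falling. These medians were all at percentile 99.99 of random lists or higher, while that of interferon response genes was at 33.3. Adjusted over the list alone, 24 male-biased and 6 complement genes fell, and 28 female-biased, 7 PPAR alpha target and 1 complement gene rose. By the same adjustment 2 T cell, 6 antigen presentation, 1 macrophage, 0 B and plasma cell and 0 blood genes rose, and 1 blood gene fell.

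Females at 18 months had 978 genes higher and 652 lower than sham males in liver, of 16659 tested, and 605 higher and 144 lower by the 2-fold limit. The female-biased list was higher in 26 of 30 members, with a median of 4.11, and the male-biased list lower in 23 of 24. Macrophage markers were higher in 11 of 18 members and lower in 0, with a median of 1.97. Trem2, a receptor of lipid-associated macrophages, stood at 6.66 in females, 1.20 in castrated males and 0.507 in sham males, and the Kupffer cell lectin Clec4f was higher at 49.3 against 15.4. For these markers the implied standard error of the sex comparison had a median of 0.694, against 0.216 for genes of like mean. Fibrosis and matrix genes were higher in 11 of 19 members, with a median of 1.25. Col1a1, a fibrillar collagen chain, was higher at 12.3 against 1.21, and Sparc, a matrix glycoprotein, at 48.4 against 14.0. Endothelial genes were higher in 8 of 13 members, with a median of 0.78, and cholangiocyte and stellate cell genes in 9 of 13. T cell markers were higher in 5 of 12 members. Cell cycle genes were higher in 5 of 18 members, including cyclin D1, encoded by Ccnd1, at 46.1 against 3.87. Adjusted over the list alone, 15 macrophage, 14 matrix, 9 endothelial, 9 cholangiocyte and stellate, 10 T cell and 8 cell cycle genes were higher, with 29 female-biased, and 24 male-biased genes were lower. Castrated males and females differed directly at 191 genes, 90 higher and 101 lower in castrated males, and at 86 and 166 by the 2-fold limit. Cyp3a44 was lower in castrated males at 6.06 against 113 in females, Ccnd1 at 9.27 and Col3a1 at 7.06 against 33.9. Plin4, a lipid droplet protein, was higher at 40.3 against 7.28. Matrix genes were lower in castrated males in 6 of 19 members, and in 15 adjusted over the list alone. Of the macrophage markers, 0 were lower over all genes by the authors' DESeq2 test and 11 adjusted over the list alone, with a median of -1.37.

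**Figure D1:**
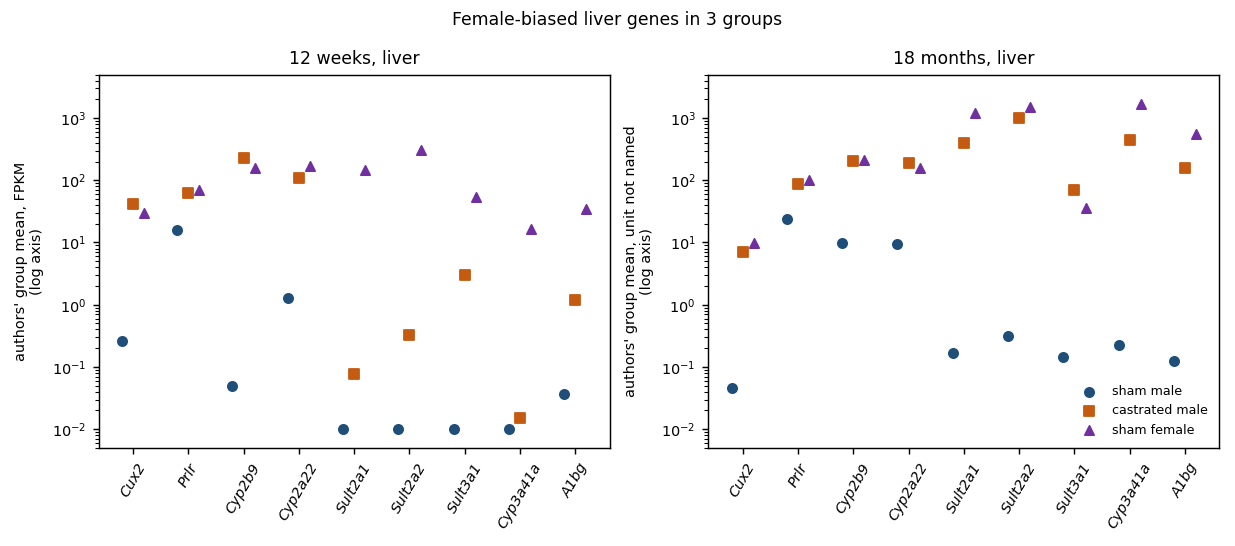
Authors' group means of female-biased liver genes on a log axis, at 12 weeks (FPKM, left) and 18 months (unit not named, right); each point is the mean of sham males, castrated males or sham females. Sult2a2 of castrated males sits at 0.329 at 12 weeks and 1015 at 18 months, and 0.01 marks genes listed at 0.

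**Figure D2:**
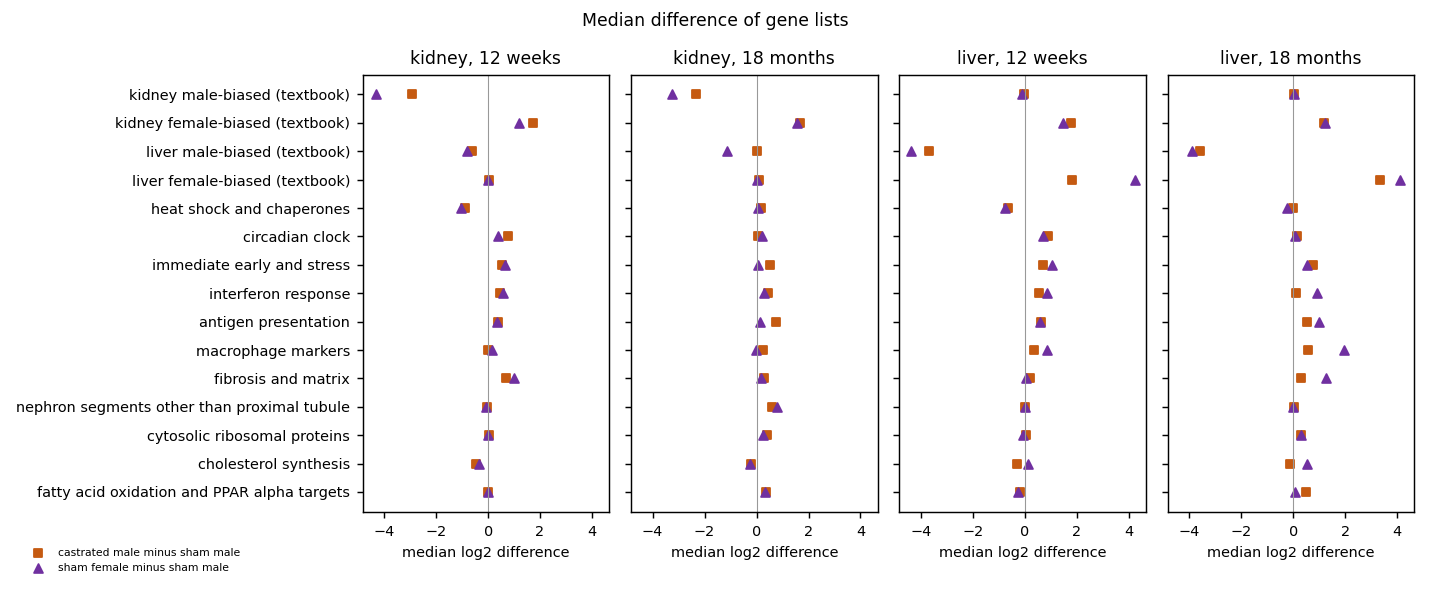
Median difference of log2(mean + 1) of gene lists in each tissue and age, for castrated males (squares) and sham females (triangles) against sham males. The female-biased liver list of castrated males lies at 1.80 at 12 weeks and 3.34 at 18 months.

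Genes that differed between the sexes were compared with their position after castration. Of 2605 genes called for sex in 12-week kidney, 98.3% had a castrated male mean on the female side of the sham male mean, and the median gene covered a fraction of 0.756 of the sex difference. In 12-week liver the share was 99.8% of 628 genes, with a median fraction of 0.714. At 18 months it was 93.4% of 2964 genes in kidney, with a fraction of 0.755, and 91.7% of 1630 genes in liver, with a fraction of 0.478. In simulations of castrated males equal to sham males, the mean shares were 59.6%, 61.0%, 63.7% and 68.6% for the same 4 tables, and the highest of 100 draws was 70.6%. The median fractions in these simulations were 0.069, 0.089, 0.07 and 0.107. Each gene's observed sex difference, which already holds the sham male error, was taken as true in the simulations, so their shares may be too low. Errors were drawn independently for each gene, so the highest draw is not a bound. At 12 weeks only genes listed for sex could be called, 3200 in kidney and 628 in liver, and the simulations drew only on these. How genes came to be listed was not modelled, so the 12-week shares may exceed the simulated ones through the listing. A share over all genes with a 2-fold sex difference, listed or not, stayed within 10 points of each reported share, but it was not simulated. Of the kidney genes called for sex at 18 months, 2059 were also called for castration in the same direction and 14 in the opposite direction. In liver at that age these numbers were 276 and 0. Genes lower in females moved toward the female side in 82.2% of cases in 18-month liver, and genes higher in females in 98.0%. In 18-month kidney these shares were 90.6% and 96.6%. The median liver gene stood 0.127 higher in castrated males and 0.139 higher in females than in sham males. Such an upward shift lowers the first share and raises the second. It was not removed from the shares and is absent from the simulations, so the 2 directions cannot be compared. Igf2, Akr1c18 and Hdc in 18-month kidney had castrated male means closer to the sham male than to the female mean. Any property of the sham male libraries enters both differences, since the sham males are the reference of each.

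**Figure D3:**
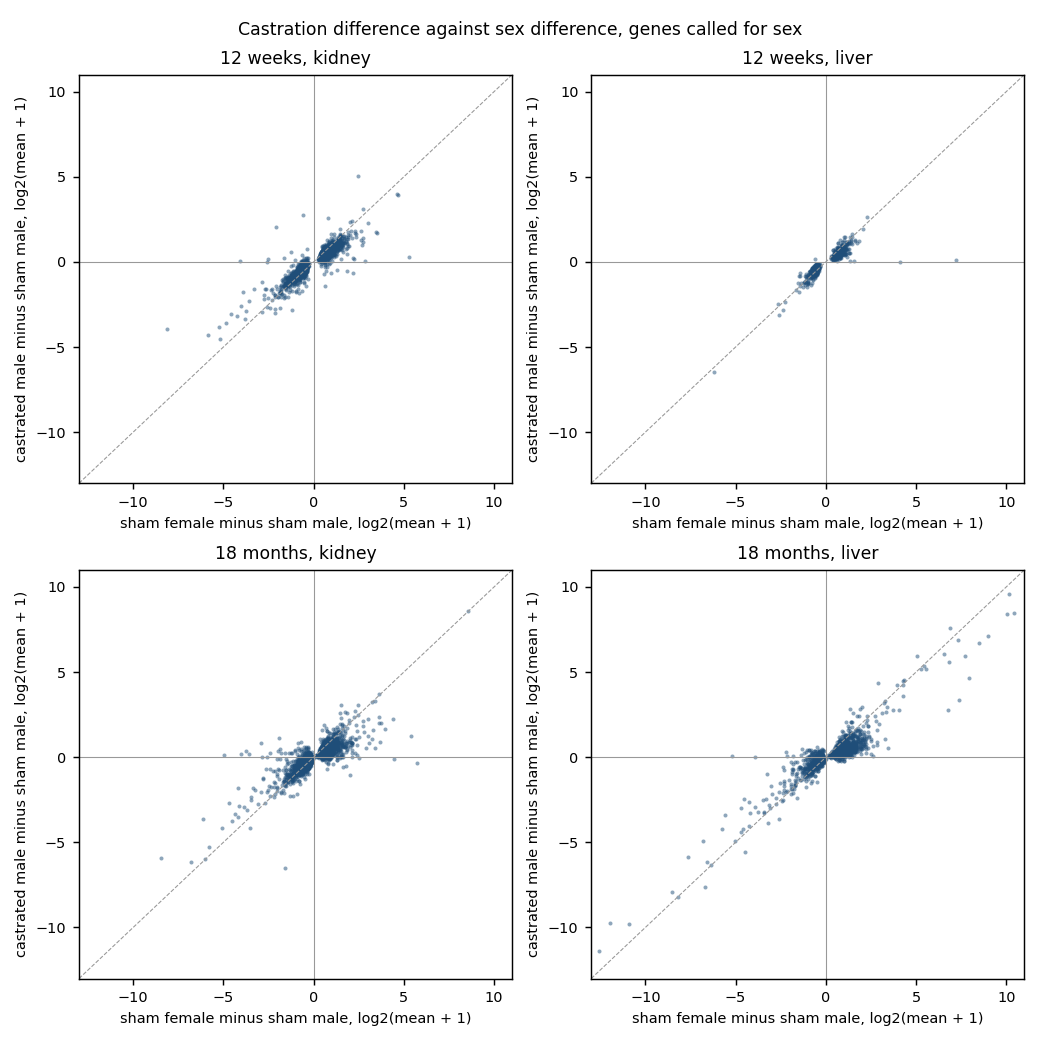
Difference of castrated males (vertical axis) against difference of sham females (horizontal axis), each from sham males on log2(mean + 1), with 1 point per gene called for sex in each tissue and age. Most points lie in the lower left and upper right quadrants, from 91.7% in 18-month liver to 99.8% in 12-week liver, and the dashed line marks equal differences.

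Kidney and liver shared 241 genes that rose and 308 that fell after castration at 12 weeks, among 3640 genes tested in both. Independence would give 38.8 and 48.0, and 45 genes changed in opposite directions. Across 6645 genes, which are not independent replicates, the Spearman correlation of the 2 tissues' differences was 0.604. At 18 months 54 genes rose and 51 fell in both tissues, where independence gives 17.8 and 22.8, and 29 were opposite, with a correlation across genes of 0.416. Between the ages, kidney shared 369 rises and 689 falls of 5316 genes tested at both, against 133.2 and 228.0 from independence, and 50 were opposite. Liver shared 77 rises and 70 falls of 7528 genes, against 14.1 and 13.8, and 5 were opposite. Prlr, Hpd, Slc22a29 and Acot3 in kidney and Cyp2b9, Cux2, Mt1 and Mt2 in liver had higher castrated than sham male means at both ages. At 12 weeks only genes listed for castration count as tested, and the listing may select genes. The numbers from independence that involve 12 weeks therefore rest on a selected set. A property shared by the sham male kidneys and livers of an age would also add to the overlap of the tissues. The tissues may come from the same animals, and the ages were not compared by a test.

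Metabolites were compared as ratios of group means, with no test and no number of animals. In kidney the sulfatide SHexCer(d34:2), a sulfated glycosphingolipid, was lower in castrated than in sham males at both ages, with log2 ratios of -3.50 at 12 weeks and -9.15 at 18 months. At 12 weeks its mean relative abundance was 11.2 in sham males, 0.992 in castrated males and 0.0415 in females. Hypotaurine was lower after castration in 12-week kidney at 0.415 against 1.46, with 0.443 in females. Of 12 methylation and sulfur compounds there, 10 were higher and 2 lower in castrated males. The glucuronosyl donor, listed as Uridine 5'-diphosphoglucuronic acid (UDP-D-glucuronate), was lower in these kidneys at 0.170 against 0.680, with 0.0581 in females. Taurocholic acid, a bile acid conjugate, was higher in 18-month kidney at 2.67 against 0.832, with 2.17 in females, while of 13 bile acids 6 were higher and 7 lower in castrated males. Serotonin was lower in these kidneys at 0.00294 against 0.00908. At least 2-fold differences were seen for 32 higher and 37 lower of 723 compounds at 12 weeks and for 70 higher and 56 lower of 985 at 18 months.

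In liver, trimethylamine N-oxide was higher in castrated males at both ages. Its mean was 0.0349 in sham males, 0.181 in castrated males and 0.473 in females at 12 weeks, and 0.0402, 0.344 and 0.522 at 18 months. L-glutamic acid was lower at 12 weeks at 0.0146 against 0.317, although the entry D-Glutamic acid stood at 0.541 against 0.621, and the glutathione analogue ophthalmic acid at 0.0202 against 0.226. Taurodeoxycholic acid was higher in 18-month liver at 21.0 against 7.58, with 22.1 in females. At least 2-fold differences were seen for 26 higher and 48 lower of 737 compounds at 12 weeks and 68 higher and 32 lower of 954 at 18 months. In serum there were 131 higher and 60 lower of 1495 entries at 12 weeks, with 25 entries near the lowest value of the table, and 84 higher and 49 lower of 868 at 18 months. Tryptophan (listed as DL-Tryptophan) was higher in 18-month serum at 8.24 against 2.72, with 6.01 in females, and the entry L-Tryptophan stood at 18.0 against 14.0. Aldosterone, a mineralocorticoid, was higher in the same serum at 0.00554 against 0.00102, with 0.0120 in females, while the other 5 of 6 steroids there were lower in castrated males. Of compounds with at least a 2-fold sex difference, castrated males lay on the female side for 94.8%, 94.4% and 88.4% in 12-week kidney, liver and serum and for 85.6%, 81.4% and 83.3% at 18 months. Sham males are the reference of both ratios, which raises these shares by an amount that the means alone cannot give.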

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

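The limit of 2 on the difference for naming genes here was chosen after the values were seen, and so was the test itself. At 18 months, the authors' log2 folds for castration differed between kidney and liver at 462 of 16514 genes, by a normal test on the implied standard errors with Benjamini-Hochberg adjustment. Whether the kidneys and livers came from the same animals is not given in the sources used here, and if they did, the errors are not independent and the number is approximate.

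Opposite calls were made in the 2 tissues at 29 genes, of which 16 had a mean of at least 5 in both. All 16 were past the test, which opposite calls nearly guarantee, so the test adds no support for these genes. The 6 with a difference of at least 2 are given as kidney minus liver, with folds from the authors' deposited table. For Cyp2a4, a steroid hydroxylase, the difference was -9.53, since the authors' deposited fold was -2.42 in kidney and 7.11 in liver. Its means went from 687 to 142 in kidney and from 1.98 to 309.9 in liver. For Slc22a26, an organic anion transporter family member, it was -7.68, with authors' deposited folds of -1.66 and 6.01. Gm6958 differed by -2.56 and Ildr2 by -2.29. Nox4, an NADPH oxidase abundant in kidney, differed by 2.52, with means from 128 to 256 in kidney and from 14.0 to 4.85 in liver. Cadm4, a cell adhesion protein, differed by 2.64. Cyp2a4 has a close sequence relative in Cyp2a5, and how reads were shared between them is not given in the sources used here.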

How the results depend on the processing

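The alternatives of a 2-fold limit without a test, a share over all genes with a 2-fold sex difference and a subtraction of genes of like GC content were chosen after seeing the data. Of 124 alternative values for 31 results, 80 stayed within 1.5 times the reported count or 10 points of the reported share, and 44 moved. The shares toward the female side were at least 88.1% (18-month liver, larger mean of at least 5), and every alternative run on them stayed within 10 points. Of 516 list medians computed, 259 lay in the outer 2.5% of random lists on either side. Of these, 0 changed sign with a pseudocount of 0.1. With members of mean at least 1, 3 did, all in 12-week kidney: adipose and cytochrome P450 genes for castration and skeletal muscle genes for sex. The cause was not tested. Over members with a mean of at least 5, castration medians in the outer 2.5% that stayed there after the GC subtraction numbered 17 of 19 in 12-week kidney, 20 of 20 in 12-week liver, 24 of 26 in 18-month kidney and 24 of 25 in 18-month liver, and 0 changed sign. In 12-week kidney those that left were antigen presentation and adipose genes. No paired analysis was possible because the labels share replicate numbers between tissues but the deposited columns are group means. Leaving out a replicate, a replicate block, another count normalization and a pseudocount inside a test could not be run for the same reason, and dropping the filter gives the reported counts, which use none. The depth behind the means is unknown.

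Called genes under an adjusted p threshold of 0.01 numbered 1791 for castration, 1673 for sex and 182 for the residual difference in 12-week kidney, and 1401, 280 and 212 in 12-week liver. At 18 months the counts that moved were 717 for the kidney residual, 865 for liver sex and 81 for the liver residual. Requiring an absolute log2 fold of at least 1 as well left 371, 515 and 30 in 12-week kidney, 347, 85 and 50 in 12-week liver, 288, 461 and 178 in 18-month kidney, and 205, 592 and 82 in 18-month liver. These fall by construction. Adjusting again over genes with a larger mean of at least 1 gave 176 for the 12-week kidney residual, and the cause was not tested. A 2-fold limit without a test gave 759, 1207 and 119 in 12-week kidney, 523 for castration and 104 for the residual in 12-week liver, 324, 500 and 232 in 18-month kidney and 749 for 18-month liver sex. At 18 months the 2-fold counts for castration and sex carry the upward shift of the means, which the authors' calls need not. For castration at that age they were 177 higher and 147 lower in kidney and 255 higher and 98 lower in liver. The side with more genes changed with this limit for that kidney comparison and also for 12-week kidney sex, at 583 higher and 624 lower, for the 12-week kidney residual, at 53 and 66, for 12-week liver sex, at 320 and 237, and for 18-month kidney sex, at 296 and 204, while the 18-month kidney residual was even at 116 and 116.

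Genes shared between the tissues numbered 281 at 12 weeks and 69 at 18 months at the threshold of 0.01, and kidney shared 643 between the ages. With an absolute log2 fold of at least 1 they were 21 and 23 between tissues, 58 between ages in kidney and 88 in liver. At a 1.5-fold limit, 174, 197 and 440 metabolites differed after castration in 12-week kidney, liver and serum, and 261, 261 and 260 at 18 months.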

Other observations

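The gene lists and their counts were planned, while every test of an explanation below was chosen after its result was seen, except the test of base composition on heat shock genes and the test on the spread of macrophage markers. In 12-week liver, urea cycle and amino acid catabolism genes rose in 5 and fell in 6 of 27 members after castration, and 7 fell adjusted over the list alone, with a median at percentile 55.96 of random lists. Tdo2, which opens the tryptophan ring, fell from 643 to 286 FPKM, and Kynu, a later step of the same pathway, fell from 68.8 to 30.2, while Hpd rose from 1292 to 3237. Glycolysis and gluconeogenesis genes fell in 6 of 20 members and rose in 0, with 7 down adjusted over the list alone and a median at percentile 49.62, or 2.04 over the 14 members with a mean of at least 5. G6pc, which releases glucose, fell from 207 to 54.7 FPKM and the glycolysis regulator Pfkfb3 from 15.9 to 3.42. In 18-month kidney, glycolysis and gluconeogenesis genes rose in 8 and fell in 2 of 20 members, with 3 down adjusted over the list alone. Pck1, which commits carbon to glucose, rose from 953 to 2247, and Pkm rose from 119 to 199. Urea cycle and amino acid catabolism genes there rose in 7 and fell in 5 of 27 members, with 8 up adjusted over the list alone. Arg2, a mitochondrial arginase, rose from 2.81 to 14.1, with 49.3 in females, and Oat, an ornithine aminotransferase, rose from 100.6 to 327, with 362 in females. In 18-month liver, 1 of 27 members of the urea cycle list and 1 of 20 of the glycolysis list fell and 0 rose, with 2 and 1 down adjusted over each list alone.

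Growth hormone axis genes rose in 2 and fell in 2 of 15 members in 12-week liver and rose in 3 of 15 in 18-month liver, or 4 adjusted over the list alone. In kidney 4 rose and 1 fell of 15 at each age. All these are castration counts, and where no other is given the count adjusted over the list alone was equal. Bcl6, a repressor of female-biased liver genes, fell in 12-week liver from 17.8 to 4.50 FPKM and in 12-week kidney from 13.0 to 2.92. In 18-month liver, Socs2, a feedback inhibitor of growth hormone signalling, rose from 2.35 to 12.8, and Ghr, the growth hormone receptor gene, fell in 18-month kidney from 295 to 164 with a female mean of 365. Acute phase genes rose in 4 and fell in 5 of 20 members in 12-week liver, also adjusted over the list alone, with a median at percentile 17.48. In 18-month liver they rose in 4 of 20 members, and in 7 adjusted over the list alone. Lcn2, an iron-siderophore binding protein, rose from 6.32 to 49.6, with 120.3 in females, and Orm3 rose from 2.66 to 18.4.

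At 12 weeks, the heat shock medians of castrated males and females lay below sham males in both tissues, and the clock medians lay above, at 0.77 in castrated males and 0.39 in females in kidney and at 0.89 and 0.70 in liver. Castration differences followed the GC content of transcripts, with Spearman correlations across genes of 0.287 in kidney and 0.166 in liver, but this is not a sufficient account, since the heat shock medians were -0.80 and -0.56 after genes of like GC content were subtracted, with 13 of 14 genes below 0 in each. The medians of all genes were 0.022 and -0.019, so a shift of all genes in the normalization does not account for it either, and the sham males may have been collected at another hour or handled differently, which cannot be separated from the groups, since collection times are not given in the sources used here. The clock differences of kidney and liver were correlated across 18 genes at 0.878, which either a shared collection time or a shared response to castration could give, and also at 0.728 at 18 months, where the list medians were 0.07 and 0.13, so a high correlation is not particular to 12 weeks. The residual medians of the heat shock list were 0.10 and 0.11 at 12 weeks, while that of the clock list was 0.245 in kidney, where 3 of 18 genes were higher in castrated males than in females and 0 lower, and 0.06 in liver. Immediate early and stress medians at 12 weeks were 0.55 in castrated males and 0.66 in females in kidney, and 0.71 and 1.05 in liver. At 18 months they were 0.53 and 0.06 in kidney and 0.75 and 0.54 in liver, so the rise after castration is not particular to 12 weeks.

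Among all liver genes called higher in females, castrated males reached a median fraction of the sex difference of 0.672 over 296 genes at 12 weeks. At 18 months it was 0.436 over 978 genes, a different set. Members of the female-biased liver list with a 2-fold sex difference at both ages went the other way. Their median fraction was 0.78 at 12 weeks and 0.92 at 18 months, higher at 18 months in 65.4% of 26 members. Whether reads shared among close relatives contribute stays open: the median of the 17 members in the Cyp, Sult and Fmo families went from 0.34 to 0.94, but the 9 outside them, whose medians differed by -0.03, went both ways, with 4 higher at 18 months, among them A1bg from 0.21 to 0.80 and Hao2 from 0.66 to 1.04. Summing the Sult3a genes did not remove the difference, with fractions 0.86 apart. The summed Sult2a means were 582.3 in sham males, 249.8 in castrated males and 674 in females at 12 weeks. At 18 months they were 517.8, 1873 and 3111, so the sum was lower after castration at 12 weeks and higher at 18 months. In sham males, Sult2a1 and Sult2a2 were listed at 0 at 12 weeks and had means of 0.17 and 0.313 at 18 months. The sham male sums thus came almost wholly from other Sult2a members, and the sums need not follow Sult2a1 and Sult2a2. These sums have no spread and a fraction was set aside at 12 weeks, where females and sham males differed by 0.21 in log2, so the Sult2a test is left open, and age, time since surgery and the separate processing of the ages cannot be told apart here.

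Macrophage, matrix and endothelial genes were higher in 18-month female than sham male livers. A lower share of hepatocytes with an unchanged mix of other cells would raise these lists by like amounts. The macrophage median exceeded the endothelial median by 1.19, with a two-sided permutation p = 0.001 over 100000 permutations of genes, which are not independent replicates. This bears only on that simple case. The mix of other cells may change as well, and the added 1 shrinks differences of low-mean markers, so a lower hepatocyte share is not excluded. A large infiltrate in 1 or a few female animals is a candidate explanation, consistent with an implied standard error of macrophage markers 3.21 times that of genes of like mean. The ratio was also 2.10 in the castration comparison, which holds no females, and 2.55 in the residual comparison, so variable infiltrates may not be specific to females. The values of single animals, which would bear on this, were not analysed here.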
